A study of Bos taurus with 15 samples.

How the data were processed

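Skin biopsies of female Holstein-Friesian cattle were flash frozen, and libraries were made with a QuantSeq 3′ mRNA-Seq forward kit, per the labels' protocols. This kit gives a single read near the 3′ end of a transcript, so counts were not scaled by gene length. The submitters' processing notes name FastQC 0.11.7, cutadapt 2.8, STAR, RSEM 1.3.1, edgeR and the genome build ARS-UCD1.2, with no order or role. The table gives whole-number read counts per gene and sample, as deposited. How the authors selected its genes is not given in the sources used here, and no gene in it has fewer than 72 counts over the 15 samples. A gene that the lists hold and the table does not was not analysed here. The authors' deposited normalised signal columns equal the CPM over the column total times a TMM factor, with a largest difference of 5.09e-11 from values computed here. The authors' group means are averages of these signal columns, and their fold ratio, log2 fold change, p-value and adjusted p-value columns compare disease with healthy, per the file headers. The deposited p-values differed from those computed here by at most 5.84e-11. All per-sample columns were matched to samples by the number that opens each title.

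Samples fell into 10 lesions and 5 healthy samples by title and description. The labels give no animal, farm, age or batch. The titles end in a code with the number 9 or 10 whose meaning is not stated: lesions 1 to 8 carry 9, and lesions 9 and 10 and all healthy samples carry 10. The sample numbers run on from the lesions into the healthy samples, so they cannot show whether a lesion and a healthy sample share an animal. No pairing was modelled. All design choices and gene lists below were fixed before the data were examined, except where said.

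Genes were named by Entrez identifier through an NCBI RefSeq gene table of the assembly ARS-UCD2.0, which matched 9249 of 9934 genes, and otherwise by the file's own symbol. 368 genes had no symbol and 215 symbols differ from those in the file. Because the table's assembly differs from the authors' build, no coordinates are given. The entry counted as DGAT2 by its Entrez number carries the symbol UVRAG in the file, so its identity is uncertain.

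Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, robust dispersion estimates, a quasi-likelihood F test of lesion minus healthy over all 15 samples, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filterByExpr filter kept all 9934 genes. CPM values refer to the TMM-scaled library. Standard errors are the log2 fold change divided by the square root of F. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 23 lists with at least 5 measured genes. Beside it stand camera with an estimated correlation and fry. The 32 lists hold 553 symbols, of which 353 were measured, and S100A7 is in a pair of lists. Lists describe groups of genes in bulk tissue, not numbers of cells. A list score is the mean over its genes of log2 CPM minus the healthy mean.

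Genes were named by a fixed rule. It took the 8 largest increases and the 8 largest decreases among called genes with a symbol, an average log2 CPM of at least 4 and all 10 lesions on the same side of the healthy mean. From each list it took the called genes with the smallest p: 2 in the direction with more calls and 1 in the other, or the gene of the highest level where none was called. This gave 76 genes. A further 31 were named after their values were seen, 22 of them because a list had 5 or fewer called members. Of the genes these choices took, 2 are not reported here. A gene with 0 counts in a group is given as a fold against a floor of 3 counts over the group, and one with 1 to 3 counts as a ratio with its exact 95% conditional binomial interval. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

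Alternatives set beforehand were DESeq2 size factors in edgeR, DESeq2 1.42.0, limma voom with sample quality weights, no filter, a stricter filter (CPM of at least 1 in at least 10 samples, which removed 339 genes), the samples of title code 10 only, each sample left out in turn, an adjusted p below 0.01, a log2 fold change of at least 2, and the other list tests. Library totals without TMM factors were added after the data were seen. The alternatives planned for normalised values or for the authors' comparison alone did not apply, since the table holds counts.

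The tests were tested on simulated counts for the same 9934 genes and library sizes. Of simulated changes, 20 of 67 genes changed 2-fold (29.9%), 59 of 67 changed 4-fold (88.1%) and 59 of 66 changed 8-fold (89.4%) were recovered, with 4 false calls among 142. A list of 20 genes raised 4-fold was called, and 0 of 20 unchanged lists were. Simulated genes were drawn independently, whereas the estimated correlation within a measured list reached 0.93. The list result therefore does not cover lists of correlated genes. Far fewer genes were changed than were called in the data, so the recovered shares need not hold for the real test.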

Results

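Udder cleft dermatitis is a skin disease of dairy cows that forms wounds on the udder. The series asked which host genes differ between severe lesions and healthy udder skin. Skin was taken with a biopsy punch from female Holstein-Friesian cattle, and RNA was measured by 3′ mRNA sequencing, which counts a short read near the end of each polyadenylated transcript. There were 10 lesion samples (numbered 1 to 10) and 5 healthy samples (numbered 11 to 15). The labels do not state that each sample came from a separate animal, so the p-values measure only the spread between these samples. Total counts over the 9934 genes of the table were 1.84 ± 0.22 M in the lesions (SD, n = 10, range 1.42 to 2.07 M) and 2.11 ± 0.31 M in healthy skin (SD, n = 5, range 1.66 to 2.51 M). No pair of samples agreed within sampling noise: the mean squared difference per gene was 4.93 to 106 times its counting variance over the 45 lesion pairs and 5.51 to 17.7 times over the 10 healthy pairs.

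Lesions had high transcripts of collagens, matrix proteases, endothelial genes, macrophage genes and inflammatory cytokines. All 13 measured hair follicle genes fell, with a median log2 fold change of -9.07, and 9 of 14 genes of sebaceous glands and fatty acid synthesis fell while 3 rose, with a median of -2.00. Basal keratinocyte scores were below every healthy sample in all 10 lesions, by little in lesions 1, 5 and 8 (-0.55, -0.58 and -0.71 against a lowest healthy score of -0.17) and by more in the other 7 (-5.11 to -3.19). Members of the list differed in lesions 1, 5 and 8. There KRT14 was above every healthy sample (3756, 5413 and 5799 CPM against 1782 to 3464 CPM). KRT15 was below every one (1.07, 4.80 and 1.77 CPM against 89.6 to 240 CPM), as was TP63. Of the 9934 genes tested with edgeR's quasi-likelihood test, 2346 were higher and 1848 were lower in lesions at an adjusted p below 0.05, which is 42.2% of the genes. With a change of at least 2-fold, 1726 were higher and 930 lower, the numbers that the authors' deposited table also marks. In 799 genes every lesion lay above every healthy sample and in 681 every lesion lay below, where chance gives 0.0666% of genes, or 6.62 genes. The first principal component held 70.2% of the variance. Healthy samples lay between -101 and -92.7 on it, lesions 2, 3, 4, 6, 7, 9 and 10 between 73.0 and 87.4, lesion 1 at 10.4, lesion 5 at -29.7 and lesion 8 at -61.2. Of the calls 55.9% were higher in lesions. With limma voom, which gave its lowest weights to lesions 5 and 8 and healthy sample 15, 2992 genes were lower.

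The 8 largest increases among well-measured genes were in SAA2, ADAM12, SLPI, CXCL8, ATP6AP1L, CXCL5, CXCL2 and SCN1A. SAA2 (ENSBTAG00000022394), an acute-phase serum amyloid, reached 85.3 ± 80.4 CPM in lesions (SD, n = 10) and had 0 counts over the 5 healthy samples. Against a floor of 3 counts over the group it was 318-fold higher (95% counting interval from 259 upwards). In lesion 8 it was 0.59 CPM. SLPI (ENSBTAG00000004148), an inhibitor of leukocyte proteases, had 853 ± 934 CPM in lesions (SD, n = 10) and 2.13 ± 2.96 CPM in healthy skin (SD, n = 5), a log2 fold change of 8.55 ± 1.61 (SE, adjusted p = 0.000777). The chemokines CXCL8 (ENSBTAG00000019716), CXCL5 (ENSBTAG00000009812) and CXCL2 (ENSBTAG00000027513), which attract neutrophils, had log2 fold changes of 7.99 ± 1.60 (SE), 7.74 ± 1.17 (SE) and 7.60 (adjusted p = 0.000391). Each of these 3 chemokines was above every healthy sample in 10 of 10 lesions. CXCL8 ranged from 23.6 CPM in lesion 8 to 3022 CPM in lesion 3. ADAM12 (ENSBTAG00000012444), a metalloprotease of activated mesenchymal cells, had 1232 counts in lesions and 1 in healthy skin, a ratio of rates of 669 (95% counting interval 120 to 26463). ATP6AP1L (ENSBTAG00000050733) had 987 counts against 2, a ratio of 268 (74.0 to 2217). SCN1A (ENSBTAG00000018520), a sodium channel known from neurons, had 577 counts against 1, a ratio of 314 (56.1 to 12405).

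The 8 largest decreases were in MOGAT2, KRTAP3-1, LOC785756, KRT85, KRT86, KRT25, PENK and SDR16C6. MOGAT2 (ENSBTAG00000037483), an acyltransferase of glyceride synthesis, had 378 ± 127 CPM in healthy skin (SD, n = 5) and 0 counts in the 10 lesions. Against the floor it was 2458-fold lower (95% counting interval from 1998 upwards). SDR16C6 (ENSBTAG00000040321), a short-chain dehydrogenase, fell from 1914 ± 586 CPM (SD, n = 5) to 1.14 ± 1.79 CPM (SD, n = 10), a log2 fold change of -10.74 ± 0.73 (SE, adjusted p = 8.33e-08). KRT25 (ENSBTAG00000030542), a keratin of the inner root sheath of the hair, had 5924 counts in healthy skin and 4 in lesions (log2 fold change -11.10 ± 0.80, SE). The hair-shaft genes KRT85 (ENSBTAG00000000400), KRT86 (ENSBTAG00000013720) and KRTAP3-1 (ENSBTAG00000052919) each had 1 count over all lesions, against 3071, 3022 and 3990 counts in healthy skin. Their ratios of healthy to lesion rates were 5652 (95% counting interval 1014 to 223300), 5561 (997 to 219739) and 7343 (1317 to 290102). LOC785756 (ENSBTAG00000045737) had 4800 counts in healthy skin against 2 in lesions, a ratio of 4417 (1222 to 36481). PENK (ENSBTAG00000004924), which encodes proenkephalin, had 3156 against 2, a ratio of 2904 (803 to 23990). Within title code 10 KRT86, KRTAP3-1 and LOC785756 were not called. BDA20, a lipocalin known as an allergen of cow dander and chosen after its values were seen, fell from 6974 ± 3602 CPM (SD, n = 5) to 5.66 ± 4.50 CPM (SD, n = 10). Hair keratins, keratin-associated proteins, serum amyloids and the KRT6 genes belong to multigene families with closely related members. Whether reads were shared between members was not tested, so the split of reads within these families is uncertain.

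**Figure D1:**
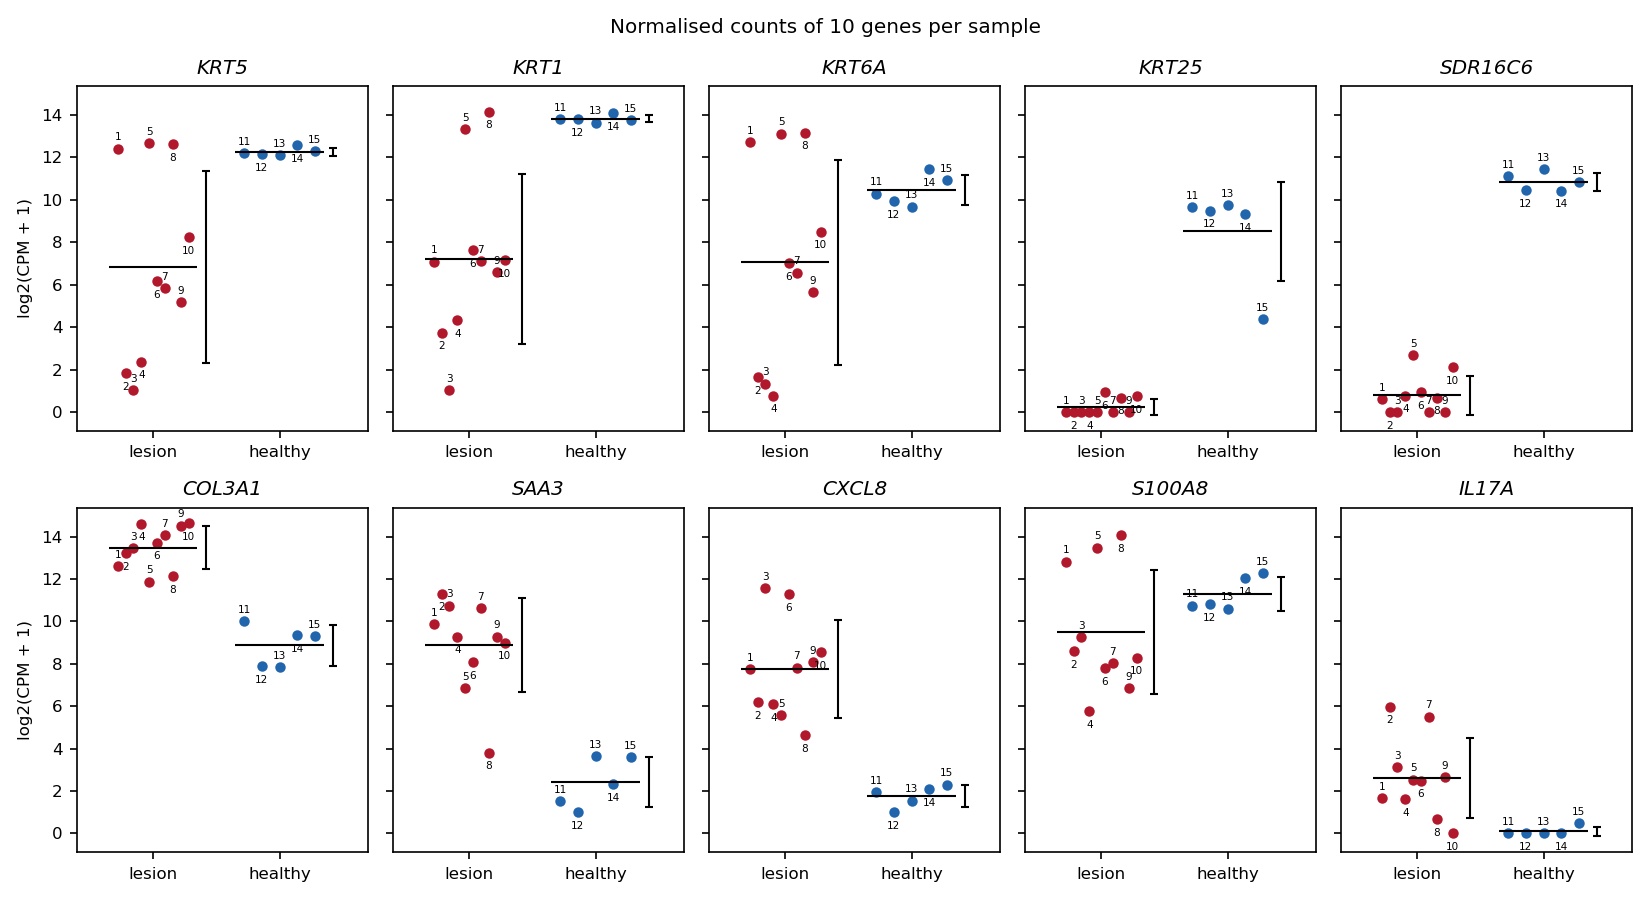
Normalised counts of 10 genes in each sample, as log2(CPM + 1) on the vertical axis, with lesions in red, healthy skin in blue, numbers naming the samples, horizontal lines at group means and bars of 1 SD of the log2 values. KRT5 in lesions 1, 5 and 8 lies at 5479 to 6497 CPM, near the healthy samples, and at 1.02 to 300.0 CPM in the other 7 lesions.

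Gene lists fixed before the data were examined described this in groups. The 23 of 32 lists with at least 5 measured genes were tested with camera, which compares a list's genes with all others, at a preset correlation of 0.01. Camera called 6 lists higher and 9 lower. With an estimated correlation between genes none of the 15 was called, and the lowest adjusted p was 0.121. Fry, which tests the direction of the list's own genes, called 16 lists, among them 14 of the 15 in the same direction. Other splits of the same samples gave up to 18 called lists with camera, with a median of 10, and up to 4 with fry.

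Connective tissue and vascular genes rose together. In the dermal fibroblast matrix list 17 of 18 measured genes rose and 0 fell, and adjusted over the list alone 17 rose. The median log2 fold change was 3.78 (camera adjusted p = 8.56e-09, adjusted p = 0.308 with an estimated correlation). COL3A1, a fibrillar collagen, reached 13947 ± 8402 CPM in lesions (SD, n = 10) against 553 ± 332 CPM in healthy skin (SD, n = 5), a log2 fold change of 4.66 ± 0.63 (SE, adjusted p = 4.95e-05). COL1A1, chosen after its values were seen, had a log2 fold change of 4.24 ± 0.58 (SE). PDGFRA, the growth factor receptor of fibroblasts, rose by 3.78 ± 0.48 (log2, SE). In the wound matrix and matrix protease list 18 of 19 genes rose (19 adjusted over the list alone, median 4.36, camera adjusted p = 7.49e-11, adjusted p = 0.254 with an estimated correlation). ADAMTS4, an aggrecan-cleaving protease, rose by 5.92 ± 0.60, and CTHRC1, a secreted protein of repairing matrix, by 5.39 ± 0.62 (log2, SE). In the endothelium list 14 of 15 genes rose (14 adjusted over the list alone, median 2.77, camera adjusted p = 1.05e-08, adjusted p = 0.254 with an estimated correlation). CDH5, the cadherin of endothelial junctions, went from 16.3 ± 2.5 CPM (SD, n = 5) to 157 ± 50 CPM (SD, n = 10, adjusted p = 2.31e-07), and KDR, the main VEGF receptor, rose by 3.23 ± 0.30 (log2, SE). All 10 lesions had list scores above every healthy sample for these 3 lists. The score was lowest in lesion 8, at 1.23 for fibroblast matrix, 1.37 for wound matrix and 0.86 for endothelium, in log2 units above the healthy mean. In the smooth muscle list ACTA2, TAGLN and LMOD1 rose and SYNM fell out of 10 genes (3 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.708). ACTA2, the smooth muscle actin that myofibroblasts also make, rose by 2.24 ± 0.41 (log2, SE). SYNM was no longer called without healthy sample 12 (adjusted p = 0.0738), nor LMOD1 within title code 10.

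Inflammatory genes were higher in most lesions. In the NF-kB cytokine and chemokine list 15 of 21 genes rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 fold change of 2.97 (camera adjusted p = 0.000283, adjusted p = 0.439 with an estimated correlation). CCL2, which attracts monocytes, went from 12.9 ± 5.0 CPM (SD, n = 5) to 158 ± 69 CPM (SD, n = 10, adjusted p = 9.45e-06). Within title code 10, 11 of 19 genes of the list rose and 3 fell, with a median of 1.23. Without lesion 3, 11 genes of the list rose. The gene that fell over all samples was IL1R2, the decoy receptor of interleukin 1 (log2 fold change -1.78 ± 0.54, SE). In the monocyte and macrophage list 13 of 14 genes rose (13 adjusted over the list alone, median 2.07, camera adjusted p = 8.13e-05, adjusted p = 0.385 with an estimated correlation). The endotoxin co-receptor CD14 rose by 3.15 ± 0.49 and the signalling adaptor TYROBP by 2.58 ± 0.47 (log2, SE). In the interferon response list 10 of 16 genes rose (11 adjusted over the list alone, median 1.54, camera adjusted p = 0.0014, adjusted p = 0.439 with an estimated correlation), among them IFI6 (2.58 ± 0.46) and IFIT5 (1.38 ± 0.25, log2, SE).

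In the neutrophil list 5 genes, among them CXCR1, CSF3R, TREM1 and NCF4, rose and LTF fell out of 8 (5 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.118), whereas fry did (0.0111). CXCR1, a receptor for CXCL8, had 58.2 ± 53.9 CPM in lesions (SD, n = 10) and 0.59 ± 0.52 CPM in healthy skin (SD, n = 5, adjusted p = 0.000501), but 0 CPM in lesion 8. LTF, lactoferrin, which glands also secrete, had a log2 fold change of -4.45 ± 0.75 (SE) and was not called within title code 10. In the antimicrobial and acute-phase list SLPI, SAA3, M-SAA3.2, LYZ and LAP rose out of 10 genes (5 adjusted over the list alone, camera adjusted p = 0.113, fry adjusted p = 5.15e-05). SAA3, a serum amyloid, went from 5.87 ± 5.02 CPM (SD, n = 5) to 891 ± 811 CPM (SD, n = 10, adjusted p = 0.000375), and LYZ, lysozyme, went from 11.6 ± 7.0 CPM (SD, n = 5) to 105 ± 64 CPM (SD, n = 10). LAP, a bovine beta-defensin, was not called with voom or within title code 10. S100A8, a calcium-binding protein of neutrophils and stressed keratinocytes chosen after its values were seen, did not pass the test (log2 fold change 0.40 ± 1.24, SE, adjusted p = 0.825). Its level was 7232, 11396.5 and 17158.5 CPM in lesions 1, 5 and 8, between 53.1 and 609 CPM in the other 7 lesions, and between 1559 and 5002 CPM in healthy skin. S100A12, chosen likewise, had the same division, with 6850 to 10000.5 CPM in lesions 1, 5 and 8, 42.6 to 876 CPM in the other 7, and 2216 to 5628 CPM in healthy skin, and was called lower with voom and within title code 10. The fold change of S100A8 had the opposite sign without lesion 8 (-0.31), and it was called lower within title code 10 (-3.75, adjusted p = 0.00732) and with voom (-2.71, adjusted p = 0.00583).

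In the pattern recognition list TLR2, TLR4, NLRP3 and LY96 rose and NOD2 and CASP1 fell out of 9 genes (4 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.462). NOD2, an intracellular sensor of peptidoglycan, fell from 135 ± 26 CPM (SD, n = 5) to 21.3 ± 15.2 CPM (SD, n = 10), while TLR2, a receptor for bacterial lipoproteins, rose by 2.10 ± 0.42 (log2, SE). CASP1 was no longer called without healthy sample 13 (adjusted p = 0.0682). In the type 17 and type 2 cytokine list IL17A and IL17F rose (2 adjusted over the list alone). IL17A had 299 counts in lesions and 1 in healthy skin, a ratio of 162 (95% counting interval 28.9 to 6438), with 62.0 CPM in lesion 2, 44.3 CPM in lesion 7 and at most 7.64 CPM in the other 8. IL17F was 192 CPM in lesion 2 and 88.6 CPM in lesion 7 (log2 fold change 5.31 ± 1.54, SE, adjusted p = 0.0129). Its healthy counts all came from healthy sample 15 (3.53 CPM), without which the log2 fold change was 9.07. Without lesion 2 the log2 fold change of IL17F was 4.34. IL17A was too low to be tested when lesion 2, 3, 6, 7, 8 or 9 was left out, which left 1 higher gene in the list, and neither cytokine could be tested within title code 10.

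Lists of immune cells with fewer than 5 measured genes were not tested as lists. NKG7 rose out of 3 T and NK cell genes (2 adjusted over the list alone), and 2 rose without lesion 1, 5 or 8 or healthy sample 12. PRDM1 fell out of 3 B and plasma cell genes (1 adjusted over the list alone), by 0.47 on the log2 scale, and lost its call without TMM factors, within title code 10, and when lesion 1, 3, 4, 6, 7 or 9 or healthy sample 11, 12, 13 or 15 was left out (adjusted p up to 0.0795 without 1 sample). JCHAIN and IRF4 had positive log2 fold changes of 1.64 and 2.31 and were not called (edgeR adjusted p = 0.144 and 0.0906). The fall of PRDM1 therefore does not describe the list. GATA2, CPA3 and FCER1A rose out of 4 mast cell genes (3 adjusted over the list alone), with FCER1A no longer called when lesion 3, 6, 9 or 10 or healthy sample 11, 13 or 15 was left out (adjusted p up to 0.0905), nor GATA2 within title code 10.

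In the hair follicle list all 13 measured genes fell (13 adjusted over the list alone), with a median log2 fold change of -9.07 (camera adjusted p = 2.82e-11, adjusted p = 0.121 with an estimated correlation). KRT35, a keratin of the hair cortex, had 804 counts in healthy skin and 1 in lesions, a ratio of 1480 (95% counting interval 265 to 58514). Healthy sample 15 was itself low in hair keratins, with 19.6 CPM of KRT25 where the other 4 had 643 to 861 CPM. In the sebaceous and fatty acid synthesis list 9 of 14 genes fell and 3 rose (9 and 3 adjusted over the list alone, median -2.00, camera adjusted p = 0.000352, adjusted p = 0.121 with an estimated correlation). The list was not called with the stricter filter, which left 11 genes (camera adjusted p = 0.0576, median -1.17), and its median was -3.00 within title code 10. ACSBG1, an acyl-CoA synthetase, fell from 137 ± 52 CPM (SD, n = 5) to 0.63 ± 0.82 CPM (SD, n = 10), and DGAT2L6, a wax and glyceride acyltransferase, had 618 counts against 1, a ratio of 1137 (203 to 44994). The genes that rose were ELOVL5, FADS1 and FADS2, which elongate and desaturate polyunsaturated fatty acids. FADS1 had a log2 fold change of 3.90 ± 0.66 and FADS2 of 7.13 ± 1.15 (SE), and ELOVL5 went from 56.2 ± 15.2 CPM (SD, n = 5) to 138 ± 26 CPM (SD, n = 10). In the gland list MUCL1, SLC12A2 and ATP1B1 fell out of 5 genes (3 adjusted over the list alone, camera adjusted p = 0.000283, adjusted p = 0.23 with an estimated correlation). MUCL1, a small secreted mucin, had 1259 counts in healthy skin and 1 in lesions, a ratio of 2317 (415 to 91588), and SLC12A2, an ion transporter of secretory cells, had a log2 fold change of -1.95 ± 0.20 (SE). List scores were below every healthy sample in all 10 lesions for hair follicle, sebaceous and gland genes. Of 4 measured adipocyte genes THRSP and PPARG fell and LPL rose (2 and 1 adjusted over the list alone). THRSP, a regulator of lipid synthesis, had 350 counts in healthy skin and 0 in lesions. Against the floor it was 215-fold lower (95% counting interval from 174 upwards). LPL, lipoprotein lipase, rose by 3.61 ± 0.59 (log2, SE).

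**Figure D2:**
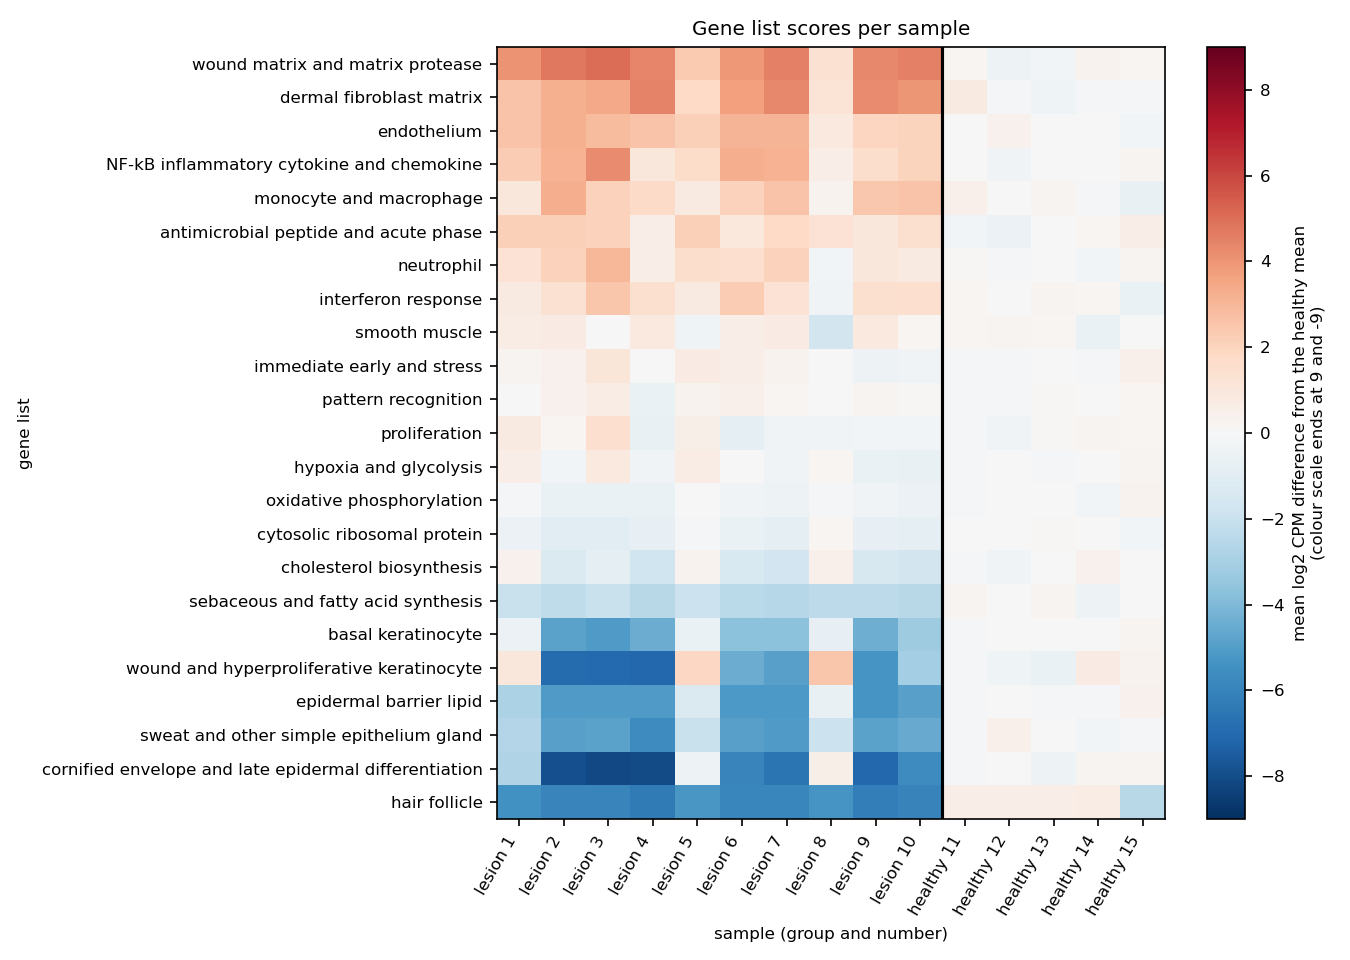
Score of each tested gene list (rows) in each sample (columns, lesions left of the black line), coloured by the mean log2 CPM of the list's genes minus the healthy mean, red above and blue below. Hair follicle scores lie between -6.40 and -5.21 in all lesions, and basal keratinocyte scores between -5.11 and -3.19 in lesions 2, 3, 4, 6, 7, 9 and 10 and between -0.71 and -0.55 in lesions 1, 5 and 8.

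Scores of the basal keratinocyte and epidermal barrier lipid lists were below every healthy sample in 10 of 10 lesions, and the barrier lipid score was -2.84, -1.33 and -0.64 in lesions 1, 5 and 8. Cornified envelope scores were below in 8 lesions and above in lesion 8 (0.54). In the basal keratinocyte list KRT15, TP63, DST, ITGB4 and LAMA3 fell out of 13 entries (5 adjusted over the list alone, median -1.41, camera adjusted p = 0.000289, adjusted p = 0.385 with an estimated correlation). KRT15, a keratin of basal and follicle stem cells, fell from 155 ± 63 CPM (SD, n = 5) to 0.94 ± 1.51 CPM (SD, n = 10). DST, a hemidesmosome plakin (the entry ENSBTAG00000051082), fell from 341 ± 26 CPM (SD, n = 5) to 94.2 ± 31.2 CPM (SD, n = 10). The other DST entry of the list was not called (log2 fold change 0.36, edgeR adjusted p = 0.51). TP63 lost its call with DESeq2 and when any 1 sample other than lesion 1, 5 or 8 was left out (adjusted p up to 0.103 without 1 sample). LAMA3 lost it without lesion 3, 4, 6, 9 or 10 or healthy sample 11, 12, 13 or 15 (up to 0.0815), and ITGB4 without healthy sample 15 (0.0624). The list had 2 lower genes without healthy sample 15, 3 in the other cases where LAMA3 was lost, and 12 with voom (list median -4.51) and within title code 10 (-4.87). KRT5 and KRT14, the main basal keratins, and KRT1 and KRT10, those of the layers above, were chosen after their values were seen and did not pass the test. KRT14 had a log2 fold change of -0.74 ± 1.59 and KRT1 of -2.30 ± 1.55 (SE). KRT5 was 4971 ± 657 CPM in healthy skin (SD, n = 5), 5479, 6497 and 6277 CPM in lesions 1, 5 and 8, and 1.02 to 300.0 CPM in the other 7. KRT1 was 14534 ± 1703 CPM in healthy skin (SD, n = 5), 10359 and 18418 CPM in lesions 5 and 8, and 1.02 to 198 CPM in the other 8, lesion 1 included at 134 CPM. KRT1 and KRT10 were called lower with DESeq2, with voom and within title code 10, and KRT5 and KRT14 with the last 2 of these.

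In the cornified envelope list KRT2 and KLK5 fell and TGM3 rose out of 17 genes (1 lower and 0 higher adjusted over the list alone, median -2.14, camera adjusted p = 8.13e-05, adjusted p = 0.439 with an estimated correlation). KRT2, a keratin of the upper epidermis, went from 77.8 ± 49.3 CPM (SD, n = 5) to 2.96 ± 8.93 CPM (SD, n = 10), of which lesion 8 had 28.4 CPM and the other 9 at most 0.66 CPM. Its log2 fold change was -4.75, and -8.76 without lesion 8. KLK5, a protease of cell shedding, lost its call with DESeq2 and when any 1 sample other than lesion 5 or 8 was left out (adjusted p up to 0.0858 without 1 sample). KRT2 was then the only lower gene without 1 sample, while DESeq2 called 4 genes of the list lower. The list had 5 lower genes without lesion 8 (list median -3.41) and 16 with voom (-7.71) and within title code 10 (-7.01). TGM3, a transglutaminase, had a log2 fold change of 2.35 ± 0.76 (SE, adjusted p = 0.0229), which was not called without healthy sample 11 or 13 (adjusted p up to 0.0578), with voom or within title code 10. In the epidermal barrier lipid list 6 of 11 genes fell (6 adjusted over the list alone, median -2.97, camera adjusted p = 0.000102, adjusted p = 0.385 with an estimated correlation), and 10 fell without lesion 8, with voom (list median -6.72) and within title code 10 (-9.31), against 3 with DESeq2. FA2H, which hydroxylates the fatty acids of ceramides, fell from 1085 ± 335 CPM (SD, n = 5) to 9.73 ± 15.1 CPM (SD, n = 10), and SPTLC3, a subunit of the first enzyme of sphingolipid synthesis, by 2.97 on the log2 scale. In the wound and hyperproliferative keratinocyte list 0 of 10 genes were called by edgeR, over all genes or the list alone. Its scores were above every healthy sample (-0.60 to 0.75) in lesions 1, 5 and 8, at 1.01, 1.85 and 2.51. In the other 7 lesions they were below every healthy sample, at -7.03 to -3.03. The list's median log2 fold change was 0.94, and 0.47, 0.42 and 0.54 without lesions 1, 5 and 8 in turn. Camera's direction was lower (adjusted p = 0.0523). The adjusted p was 0.589 with an estimated correlation. Camera at the preset correlation called the list lower without lesion 1 (0.0163), lesion 5 (0.0198) or lesion 8 (0.0234), with the stricter filter (0.0347), without TMM (0.029), within title code 10 (0.000182) and with voom (0.000572). Within title code 10, 6 of the 10 genes were lower (list median -3.39), with voom 9 (-4.65), and 1 with DESeq2 and without lesion 8. KRT6A, the wound keratin, chosen after its values were seen, had 6750, 8897 and 9214 CPM in lesions 1, 5 and 8, 0.70 to 361 CPM in the other 7, and 1564 ± 812 CPM in healthy skin (SD, n = 5). S100A7, an antimicrobial protein of stressed keratinocytes that the antimicrobial list also holds, was below every healthy sample in 10 of 10 lesions but did not pass the test (log2 fold change -3.68 ± 1.58, SE, adjusted p = 0.0746). It passed without lesion 8, with a log2 fold change of -5.98, and with DESeq2, with voom and within title code 10.

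In the cholesterol biosynthesis list INSIG1, LSS, SC5D and HSD17B7 fell out of 19 genes (2 adjusted over the list alone, median -0.77, camera adjusted p = 0.00835, adjusted p = 0.58 with an estimated correlation, fry adjusted p = 0.0712). SC5D, a sterol desaturase, fell by 0.91 on the log2 scale. LSS lost its call when any 1 sample other than lesion 1, 5 or 8 was left out (adjusted p up to 0.103), and HSD17B7 without lesion 2, 3, 4 or 7 or healthy sample 11, 13 or 14 (up to 0.11), in which cases 2 genes of the list were lower. In the list 17 fell with voom (list median -1.27) and 18 within title code 10 (-1.58). Lesions 1, 5 and 8 had scores of 0.35, 0.35 and 0.48 on this list, and the other 7 had scores between -1.81 and -0.91. In the oxidative phosphorylation list 9 of 22 genes fell (9 adjusted over the list alone, median -0.31, camera adjusted p = 0.00857, adjusted p = 0.481 with an estimated correlation), with 4 lower without healthy sample 15 and 5 without lesion 4 and within title code 10, where the list was not called (camera adjusted p = 0.0589). UQCRC1 of complex III fell by 1.23 and NDUFV1 of complex I by 0.72 on the log2 scale. In the cytosolic ribosomal protein list 11 of 21 genes fell (12 adjusted over the list alone, median -0.53, camera adjusted p = 8.13e-05, adjusted p = 0.46598 with an estimated correlation), and all 21 fell without lesion 8 and with voom. RPL8 had a log2 fold change of -0.79 ± 0.16 and RPL18 of -0.65 ± 0.13 (SE). In the hypoxia and glycolysis list SLC2A3, P4HA1 and ADM rose and EGLN3, PDK1 and ALDOA fell out of 17 genes (3 and 3 adjusted over the list alone, camera adjusted p = 0.96). P4HA1, a collagen prolyl hydroxylase subunit, rose by 2.28 ± 0.40 (log2, SE). ALDOA was not called without healthy sample 15 (adjusted p = 0.0948). Of 19 proliferation genes RRM2 alone was called (log2 fold change 1.25 ± 0.41, SE, adjusted p = 0.0213), with 0 adjusted over the list alone and not without healthy sample 12 (adjusted p = 0.0552), and the list was not called (camera adjusted p = 0.896). In the immediate early list NR4A1, NR4A2, HSPH1 and GADD45B rose and DUSP1 fell out of 15 genes (4 and 1 adjusted over the list alone, camera adjusted p = 0.741). GADD45B was not called without healthy sample 13, 14 or 15 (adjusted p up to 0.0718). MITF, the only measured melanocyte gene, did not pass the test (log2 fold change 0.28 ± 0.56, SE, adjusted p = 0.714). Genes of the milk protein, skeletal muscle and erythrocyte lists were not analysed here.

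**Figure D3:**
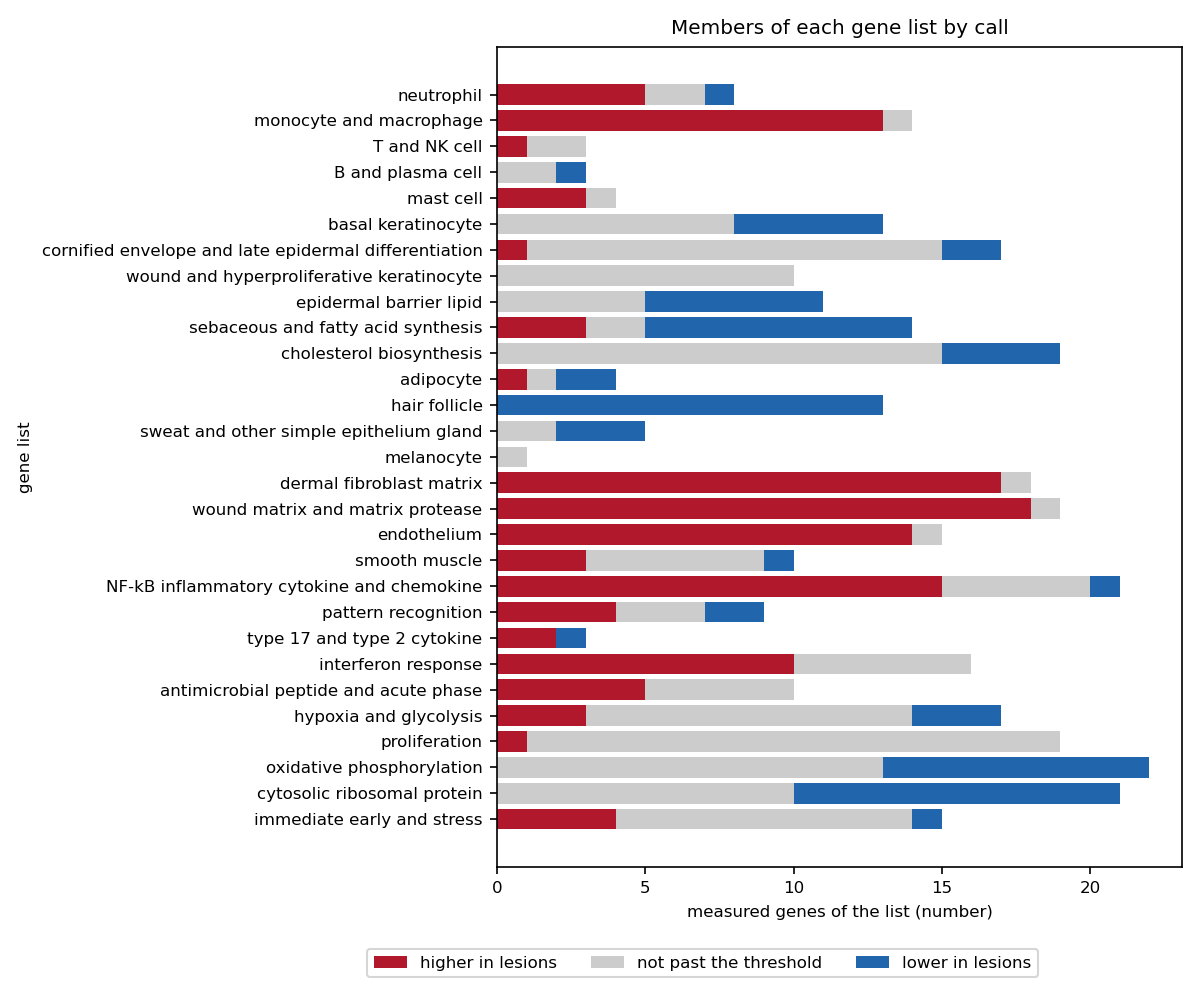
Number of measured genes of each list that were higher in lesions (red), lower (blue) or not past the threshold (grey) by edgeR at an adjusted p below 0.05. The dermal fibroblast list has 17 of 18 genes higher and the hair follicle list 13 of 13 lower.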

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

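Of the tests in this part, the comparisons of the explanations for the epidermal and hair follicle patterns and of the title codes were chosen after the results were seen. The split tests were set before.

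For the number of called genes, 1 of 100 splits of the 15 samples into groups of 10 and 5, the real one, gave 4194. The highest other gave 0 (edgeR), with at most 2304 genes at an unadjusted p below 0.05, against 5035 for the real one. Every other split mixes lesion and healthy samples within a group, which widens its spread and lowers its calls. For changes of at least 2-fold the real split gave 2656 and the highest other 0, again 1 of 100. For the number of lists called by camera chance cannot be excluded: 23 of 100 splits gave at least the real 15, and the highest other gave 18. For lists called by fry 1 of 100 splits, the real one, reached 16, and the highest other gave 4. The 100 splits were drawn from 3003, so the lowest share they could show was 1 of 100, which limits chance without excluding it. They do not address whether the samples came from separate animals. A difference between title codes 9 and 10 does not account for the calls, since 78.9% of the called genes were also called in the same direction within code 10, where 2 lesions met 5 healthy samples. A smaller contribution of the codes stays open.

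The pattern in the epidermis was that basal keratinocyte scores ran from -5.11 to -0.55 over the lesions. Fibroblast matrix, endothelium and NF-kB scores were above every healthy sample in 10 lesions. Macrophage and interferon scores were above in 9, lesion 8 excepted. The neutrophil and pattern recognition lists were not called by camera. For library size as the source, the largest and smallest effective libraries differed by 0.83 on the log2 scale, against a range of 4.55 in the basal score. Scores are already scaled for library size, so this comparison decides little. Total counts of lesions 1, 5 and 8 (1.84, 1.81 and 2.03 M) lay within the range of the other lesions (1.42 to 2.07 M), so totals did not separate them. A lower share of keratinocytes alone would raise other tissue alike, but fibroblast minus smooth muscle scores were 1.90 to 3.80 in lesions and -0.53 to 0.61 in healthy skin, so at least a further change is needed. How much epidermis each biopsy held is not given in the labels and stays open, as does the stage of each lesion, which no label gives.

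Healthy sample 15 was far below the other healthy samples in hair follicle genes, with a list score of -2.51 against 0.57 to 0.69. Low depth is excluded, because its total of 2.51 M counts was the highest of the healthy samples. A biopsy without follicles and their glands is argued against by its sebaceous score of -0.0398, inside the range of the other 4 (-0.49 to 0.26). A lesion labelled as healthy is argued against by its wound matrix score of 0.19, inside the healthy range (-0.45 to 0.34) and below all lesions (1.37 to 5.01). The phase of the hair cycle was not tested, nor was any explanation beyond those above.

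A sample far from the rest of its group was looked for in 266 groups of values, and 37 were found. Chance would give 13.3 if the groups were independent and had continuous values. Several groups share a sample and related genes, and any count is flagged where all other samples have 0. The excess over 13.3 is therefore not interpreted. In log2 CPM healthy sample 15 was lowest in KRT35 (3.72), KRT25 (4.37), KRT86 (2.71), KRT85 (4.98), KRTAP3-1 (2.71) and BDA20 (10.64). The same sample was highest in the epidermal barrier lipid score (0.40), the immediate early score (0.43), TP63 (5.27), ADAMTS4 (2.42) and IL17F (2.19). Healthy sample 11 was highest in the fibroblast matrix score (0.78) and lowest in NOD2 (6.51). Healthy sample 12 was lowest in CCL2 (2.35) and IFIT5 (5.31). Lesion 8 was lowest in the endothelium score (0.86), the smooth muscle score (-1.66), CXCL5 (2.53), M-SAA3.2 (2.79), LMOD1 (3.39) and CXCR1 (0.045, a count of 0), and highest in KRT2 (4.88). Lesion 1 was lowest in FCER1A (1.40), and lesion 4 in CASP1 (0.045, a count of 0). The remaining values come from genes with 0 counts in every other sample of the group: ADAM12 (0.51), IL17A (0.51) and ATP6AP1L (0.86) in healthy sample 15, SCN1A (0.76) in healthy sample 14, DGAT2L6 (0.70) in lesion 8, KRT35 (0.71) and PENK (1.16) in lesion 5, MUCL1 (0.76) in lesion 10, KRT86 (0.55) in lesion 7, KRT85 (0.58) and LOC785756 (0.97) in lesion 6, and KRTAP3-1 (0.65) in lesion 1.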

How the results depend on the processing

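Library totals without TMM were added after the data were seen, and all other alternatives were planned. No gene called in the main test was called in the opposite direction under any of the 22 refits, and shared calls ranged from 3308 (title code 10) to 4194 (no filter, which removed no gene and so tests nothing). Counts stayed within 1.5 times except for lower genes. With voom there were 2992 lower genes and 1483 at least 2-fold lower, and within code 10 there were 1501 at least 2-fold lower. The cause was not tested. The stricter thresholds give fewer by construction: 1027 lower at an adjusted p below 0.01, and 961 higher and 390 lower at a log2 fold change of at least 2. The share of higher calls was 48.5% with voom and 61.3% without healthy sample 15, against 55.9%. Leaving out each sample gave 2046 to 2537 higher and 1353 to 2420 lower genes, 1621 to 1826 and 759 to 1213 of them at least 2-fold, with the highest lower counts without lesion 8 and the lowest without healthy sample 15. It left 6 lists called higher and 9 to 10 called lower.

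With an estimated correlation camera called 0 lists higher and 0 lower. Adjusted p was 0.121 for hair follicle and sebaceous, 0.23 for gland, 0.254 for wound matrix and endothelium, 0.308 for fibroblast matrix, 0.385 for macrophage, basal keratinocyte and barrier lipid, 0.439 for cornified envelope, NF-kB and interferon, 0.46598 for ribosomal, 0.481 for oxidative phosphorylation and 0.58 for cholesterol. Fry called neutrophil (0.0111) and antimicrobial (5.15e-05) and did not call cholesterol (0.0712). The sebaceous list was not called with the stricter filter (0.0576), which removes genes absent from lesions, and oxidative phosphorylation was not called within code 10 (0.0589). The wound keratinocyte list was called lower with the stricter filter (0.0347), within code 10 (0.000182), with voom (0.000572) and without TMM (0.029), and ranged from 0.0163 to 0.0951 over samples left out. Lists that were not called turned direction: hypoxia with the stricter filter (0.979), within code 10 (0.129) and with voom (0.853), proliferation (0.295) and immediate early (0.162) within code 10. Without single samples hypoxia ranged from 0.798 to 0.984 and proliferation from 0.612 to 0.951.

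KRT6A turned lower within code 10 (-2.93) and with voom (-4.86), S100A8 within code 10 (-3.75) and with voom (-2.71) and between -0.31 and 0.74 over samples left out, and MITF with voom (-0.0078). Code 10 holds none of lesions 1, 5 and 8. Its lesions 9 and 10 were below every healthy sample in KRT6A (48.8 and 361 CPM against 824 to 2794 CPM). The same held for S100A8 (115 and 311 CPM against 1559 to 5002 CPM), so the lower values within code 10 follow from its samples. For the other turns the cause was not tested, although voom gave lesions 5 and 8 weights of 0.39 and 0.21. The wound keratinocyte list had 9 lower genes with voom and 6 within code 10, against 0. The stricter filter removes genes low in lesions and left 3 of 13 hair follicle genes, all lower (list median -2.88), and 4 of 11 barrier lipid genes, 1 lower (-1.36). It left 11 of 13 basal keratinocyte genes, 3 lower against 5, and 13 of 17 cornified envelope genes, 0 lower against 2. Hypoxia genes lower were 7 within code 10 and 6 with voom against 3, and immediate early genes 5 and 4 against 1. Gland genes lower were 5 with voom and within code 10 against 3. Of 98 named genes that were called, 98 kept their call with DESeq2 size factors, 97 without TMM and 96 with DESeq2 and with voom, and 85 of 94 within code 10. Of the named genes that were not called, 3 were called with DESeq2, 8 with voom and 7 within code 10. In simulation 29.9% of 2-fold changes were recovered at these library sizes and sample numbers, with far fewer genes changed than were called in the data. Other depths were not simulated.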

Other observations

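The gene families described here, and their tests, were chosen after the data were seen. Families were formed from symbols with a shared stem, and 306 of them with at least 5 measured genes were compared with all tested genes by a hypergeometric test, adjusted over both directions. Genes of a family are not independent, so these p-values describe the list of calls. Of 24 collagen genes 22 were higher where 5.67 were expected (adjusted p = 1.53e-09), with a median log2 fold change of 4.25. COL4A5 alone was lower (-2.32, adjusted p = 0.0351). No collagen gene was lower with DESeq2 or without lesion 4, 7 or 9 or healthy sample 11, 12, 13 or 14, where the count was 0, and 2 were with voom and within title code 10. Of the collagens, 9 of the 24 are in the fixed lists. All 7 ADAMTS proteases were higher (adjusted p = 0.00415), and 10 of 12 MMP proteases (0.00266) with MMP7 lower (-5.89). The fixed lists hold 1 of these ADAMTS genes and 7 of the 12 MMP genes. Of 14 genes with a TSPAN symbol 12 were higher and 0 lower (adjusted p = 0.000335), none of them in the fixed lists. Tetraspanins with other symbols were not counted there, such as CD63, which was higher (1.72), and CD82, which was lower (-1.09). All 6 SMAD genes, which carry TGF-beta and BMP signals, were higher with a median of 0.77 (adjusted p = 0.0151), led by the inhibitory SMAD6 (2.83). The number was 4 without healthy sample 15, and 5 without healthy sample 11 or 12, with voom and within title code 10. All 5 measured HOXB genes, which mark position along the body axis, were higher with a median of 3.44 (adjusted p = 0.0498). Of 12 genes with a CLEC symbol, which not all C-type lectins carry, 9 were higher (adjusted p = 0.0186). CLEC2A (-5.98) and CLEC16A (-0.96) were lower. Of 46 genes with a CD symbol 26 were higher and 3 lower (adjusted p = 0.000335), and within title code 10, 23 of 44 were higher and 6 lower. Of the genes with a CLEC symbol 6 of 9 were higher there. The median of each of these families kept its sign in all 22 refits, the scalings included.

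Keratins gave the only family past the threshold in the lower direction, with 14 of 24 lower and 0 higher (adjusted p = 0.0026, median -5.20). The fixed lists hold 18 of the 24, and the keratins of the hair follicle list are all among the 14 lower ones. The family result therefore repeats that list's result in part. The number lower was 23 with voom and 0 of 8 with the stricter filter, which removes keratins absent from lesions, and the median stayed below 0 in all refits.

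FADS2 and FADS1 rose where most other genes of the fatty acid list fell. FADS2 was 33.9 to 153 CPM in lesions 1 to 4, 6, 7, 9 and 10, 7.80 CPM in lesion 5 and 1.18 CPM in lesion 8, against at most 1.53 CPM in healthy skin.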
